A study of Mus musculus with 7 samples.

How the data were processed

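The series labels 7 samples of mouse spleen CD8 T cells: 3 libraries with an antibody to LEF1, 3 with an antibody to TCF1 and 1 input control. Per the labels' protocols, sorted cells were fixed, permeabilised and incubated overnight with the antibody, a protein A/G and micrococcal nuclease fusion cut the DNA around bound antibody, and the released fragments were made into libraries. Groups and replicate numbers were taken from the sample titles. The input control comes from another sort gate than the antibody libraries, and a peak list of it was not analysed here. A positive control with an antibody to a histone mark is named in the protocol and was not analysed here.

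Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore 0.6.6, Bowtie2 2.4.4, Picard, MACS3 3.0.3 and deepTools 3.5.1, with genome build GRCm38.p6. The peak caller's options, filters and control are not given in the sources used here. The deposited files are peak lists, and the peak names carry the library, so the authors called peaks per library and not on pooled libraries. The fold enrichment of each peak is a ratio of the signal at its summit to the local background, as deposited by the authors. The deposited p-value and q-value of each peak are given as −log10 values, and the smallest deposited −log10 q was 2.00 to 2.06 in the 6 lists. The deposited score is a whole number made from the −log10 q. The summit is the deposited offset from the peak start. These values belong to the authors' lists and were used to describe, rank or filter peaks within a list, and the fold enrichment also to read the relative depth of the libraries (below). How duplicates and repeats were treated decides which peaks exist, and longer lists overlap more, so similarity, overlap shares, gene-end shares, factor-only and factor-specific regions and gene lists were also computed with lists of equal size.

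Absolute read totals were not given. Relative depth was read from the lowest fold enrichments: where the local background is 1 read, the fold enrichment rises in equal steps, and a step is worth 0.309 to 0.396 of a control read. Of 2137 to 5197 such peaks per library, 100% fell on a whole step within a tolerance of 0.02. The inverse of the step is the depth relative to the control. The commonest background per 1000 bp of the shortest peak was 2.25 to 2.26 in all 6 libraries, so the control total was taken to be the same in all.

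Intervals listed with several summits were counted once, and peaks on chromosomes 1 to 19, X and Y were used. Coordinates are 1-based on GRCm38.p6. A region is a merged interval over the 6 libraries (overlap of at least 1 bp), and a factor holds it when at least 2 of its 3 libraries have a peak in it. Similarity of lists is the Jaccard index of covered bases. Equal list sizes take the 11423 peaks with the highest −log10 q of each library, the length of the shortest list. Differences between group means were tested with exact permutation tests over the 20 assignments of 3 and 3 libraries (smallest two-sided p 0.1), and the similarity over the 10 splits (smallest one-sided p 0.1). Shares have 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only.

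Gene positions came from a RefSeq gene table of the same build with 21887 protein-coding genes. All 236 genes of the 13 lists were found in it. The table used here has neither strand nor exons, and no genome sequence was used. The planned promoter share, meant to use transcript starts, was therefore replaced by the share of summits within 1 kb of either end of a protein-coding gene, and the promoter-only gene lists by regions at gene ends. Exons and introns were not told apart. The planned motif counts and the filter on repeats were not run. A gene's regions are those touching the gene body or 10 kb on each side, and regions near neighbouring genes count for each. Gene lists were compared with 10000 random lists in which each gene was replaced by one of the 100 protein-coding genes nearest in length (gene permutation test, two-sided, smallest p 0.0002, Benjamini-Hochberg adjustment over 13 lists and both factors).

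The named genes follow a rule fixed before the data were examined, as were the groups, lists, tests and other settings to be tried. Always named were 20 genes of the factors and of T cell biology, then the 4 members of each list with the most regions, the 10 regions of all 6 libraries with the best mean rank of fold enrichment, and the best 8 regions found in every library of one factor and none of the other, each by its nearest protein-coding gene. Some genes that this rule names are not reported here. The best-ranked regions with equal list sizes, and further list members named as examples, were added after their values were seen.

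The code was tested on simulated data. Of 200 planted LEF1-specific and 200 planted TCF1-specific regions, 100% were recovered. They were planted in every library of one factor and none of the other, among libraries of similar size. This checks the code and not the power on the real lists of unequal length. For LEF1 regions and lists of 20 genes, the list test called 3% of 100 lists with no effect, 66% of lists raised 2-fold, 99% raised 3-fold and 100% raised 5-fold, at an unadjusted p below 0.05. Counts in the raised lists followed a Poisson distribution around the mean of genes of similar length, and real counts may vary more. Alternatives were a stricter threshold (−log10 q of at least 5), equal list sizes, reciprocal overlap of 0.5, peaks reduced to 75 bp on each side of the summit, holding in 3 of 3 libraries, a distance of 2500 bp to gene ends, gene ends only, 50 kb around genes, replicate numbers as pairs, and leaving out each library in turn. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.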

Results

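CUT&RUN, in which an antibody directs a nuclease to cut the DNA around a bound protein, was used to map LEF1 and TCF1 in naive CD8 T cells of mouse spleen. LEF1 (gene Lef1) and TCF1 (gene Tcf7) are related DNA-binding proteins of the HMG family, known for their roles in T cell development and in Wnt signalling. The cells carried the transgenic P14 T cell receptor and were sorted as CD44-negative naive cells, that is, T cells that have not met antigen. Peak lists of 3 LEF1 and 3 TCF1 libraries were compared. An input control, sorted through another gate (CD44-positive, Ly5.1-negative), is labelled in the series, and a peak list of it was not analysed here. The labels do not say whether the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

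The LEF1 libraries held 27666, 37646 and 23704 peaks in replicates 1, 2 and 3, and the TCF1 libraries held 25623, 22901 and 11423. The mean was 29672 ± 7184 peaks for LEF1 (SD, n = 3) and 19982 ± 7537 for TCF1 (SD, n = 3). The difference of 9690 peaks exceeded either SD, but the ranges of the groups overlapped (exact permutation test, two-sided, p = 0.2, where 3 against 3 libraries allow no p below 0.1). Peaks covered 10.7 to 16.1 Mb in the LEF1 libraries and 4.33 to 11.7 Mb in the TCF1 libraries, with median widths of 322 to 376 bp. Read totals were not given in the files. The steps between the lowest fold enrichments gave each library's depth relative to the control used in peak calling: 2.89, 2.66 and 2.76 for LEF1 replicates 1 to 3 and 2.70, 2.52 and 3.23 for TCF1 replicates 1 to 3. TCF1 replicate 3, the library with the fewest peaks, thus had the highest relative depth.

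**Figure D1:**
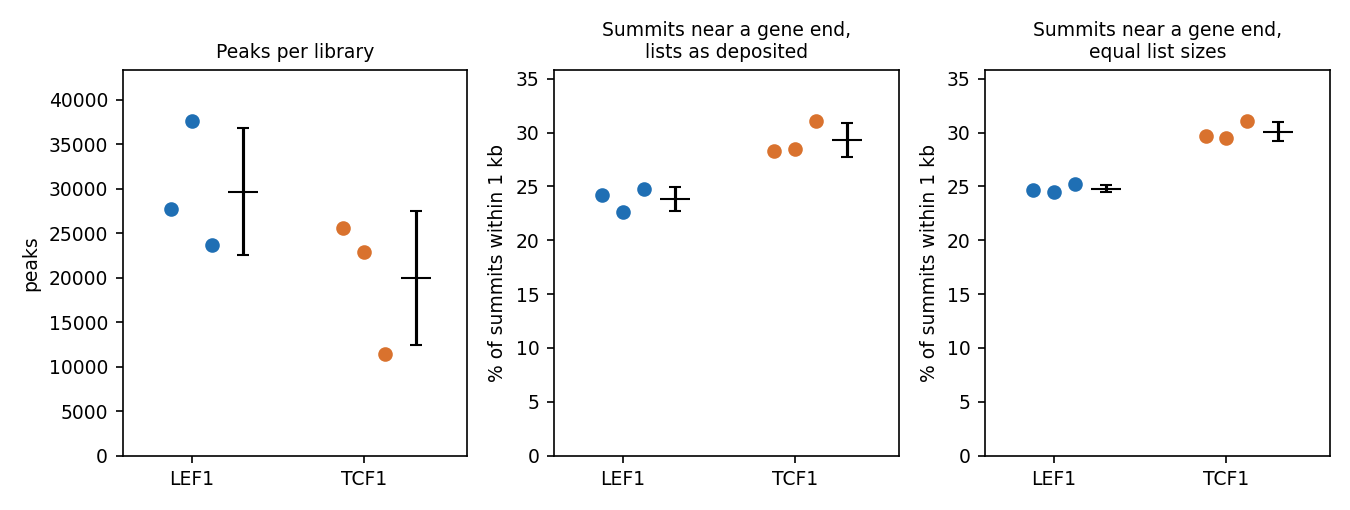
Each point is a library (3 LEF1, 3 TCF1), with the mean and SD drawn beside the points. The left panel gives the number of peaks, and the other panels give the percentage of peak summits within 1 kb of either end of a protein-coding gene, for the lists as deposited and for the 11423 strongest peaks of each library. The LEF1 libraries lie between 22.6% and 24.8% and the TCF1 libraries between 28.3% and 31.1% in the middle panel.

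Whether LEF1 and TCF1 occupy the same places was asked first. In the lists as deposited, nearly all regions held by TCF1 were also held by LEF1, and Lef1 and Tcf7 themselves were among the genes with shared regions. The 6 libraries together marked 38231 regions, of which LEF1 held 27401 and TCF1 held 21214, counting a region as held when at least 2 of the 3 libraries of a factor had a peak in it. Both factors held 20475 regions, which was 96.5% of the TCF1 regions (95% exact binomial interval 96.3 to 96.8) and 74.7% of the LEF1 regions (74.2 to 75.2). When the TCF1 regions were placed at random on their chromosomes, 1.31% ± 0.076 overlapped a LEF1 region (SD over 100 shuffles), and when they were shifted by 10 to 50 kb, 5.91% ± 0.145 did. Neither placement was kept to open DNA, and no list of a non-specific antibody or of the input control was analysed. These values therefore do not separate binding by both factors from cuts at DNA open in these cells. Whether either antibody also recognises the other factor was not tested. With equal list sizes 88.5% of the TCF1 regions and 88.1% of the LEF1 regions were shared. Lists of equal size left 11219 TCF1 and 11265 LEF1 regions held. Both shares then had to be close, which says nothing on the cause of the asymmetry. The LEF1 share was 49.4% when a peak in all 3 libraries was required, 39.9% without TCF1 replicate 1 and 40.0% without TCF1 replicate 2, where the short list of TCF1 replicate 3 had to hold the region, against 74.7% without TCF1 replicate 3.

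At Lef1 itself (chromosome 3, 131110297 to 131224357 in GRCm38.p6), the gene body and 10 kb on each side held 26 LEF1 and 20 TCF1 regions, all 20 of the latter shared. Tcf7 (chromosome 11, 52246527 to 52283383) held 13 LEF1 and 11 TCF1 regions, again with all 11 shared. The strongest Tcf7 region, present in all 6 libraries, spanned one end of the gene (52283104 to 52284704). Of the relatives of these factors, Tcf7l1 held 3 LEF1 and 2 TCF1 regions, and Tcf7l2 held 4 of each. Axin2, a feedback inhibitor of Wnt signalling, had a region in all 6 libraries inside the gene (chromosome 11, 108920018 to 108923301).

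Genes of naive and stem-like T cells held regions of both factors. Ccr7, which encodes a chemokine receptor for entry into lymph nodes, held 11 LEF1 and 10 TCF1 regions within 10 kb of a gene of 10.9 kb. Il7r, the gene of the IL-7 receptor alpha chain, held 4 and 2. Bach2, a transcriptional repressor that restrains effector differentiation, held 34 LEF1 and 26 TCF1 regions over 348 kb. Slamf6, a surface receptor used as a marker of stem-like CD8 T cells, held 5 and 4. Cd8a held 6 LEF1 and 4 TCF1 regions and Cd4 held 2 of each. Id3 held 2 TCF1 and 1 LEF1 region, while Id2 held 2 of each and Myb held 1 of each. Of the effector genes, Gzmb (granzyme B, 3.5 kb), Ifng (interferon gamma, 4.8 kb) and Pdcd1 (the receptor PD-1, 14.2 kb) held 1 LEF1 and 1 TCF1 region each, where the means over all protein-coding genes, not matched on length, were 1.34 and 1.08. Ranked by fold enrichment within each list, these regions had mean percentiles of 42.8, 75.5 and 2.51, where low values are the strongest peaks. Tox, a regulator of exhausted T cells, held 12 LEF1 and 7 TCF1 regions, and Prdm1, the gene of the repressor Blimp-1, held 8 and 6.

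**Figure D2:**
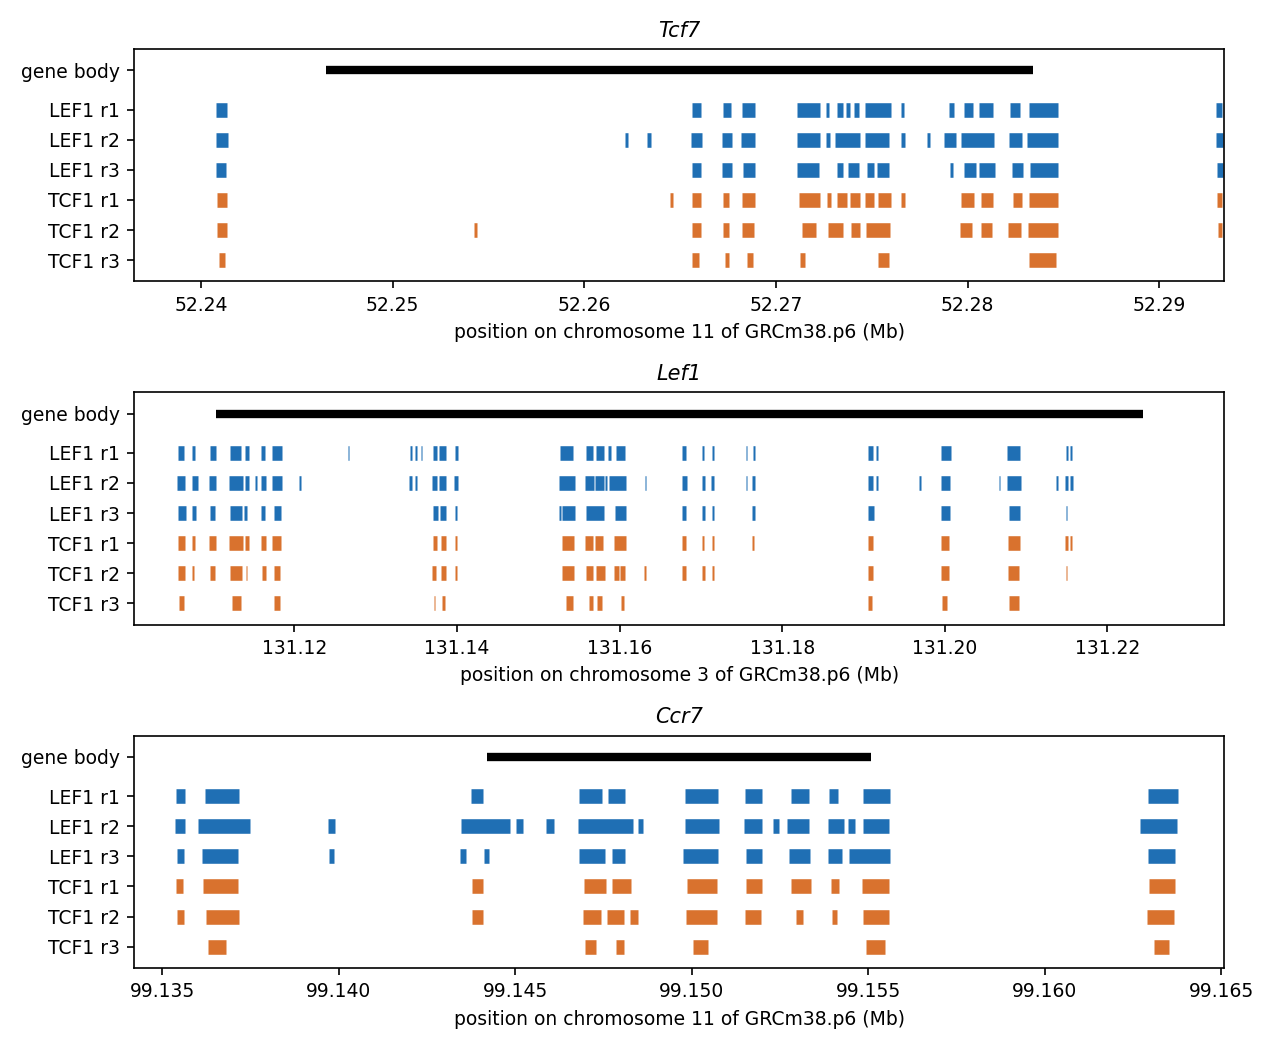
Peaks of each library at Tcf7, Lef1 and Ccr7, drawn to scale on GRCm38.p6 with the gene body as a black bar and 10 kb shown on each side. LEF1 and TCF1 peaks mostly fall on the same places at the 3 loci, and TCF1 replicate 3 has the fewest peaks at each, for example 7 at Tcf7 against 14 to 17 in the other libraries.

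Ranked by the authors' fold enrichment within each list, the best region of all 6 libraries lay inside Pdcd1lg2, the gene of the PD-1 ligand PD-L2 (chromosome 19, 29453760 to 29455026, fold enrichment 115.64 to 293.9). The next lay 12.3 kb from Dapl1, a gene expressed in naive T cells (chromosome 2, 59469070 to 59472325, fold enrichment 117 to 264). Others among the 10 best were near one end of Ska2 (chromosome 11, 87108496 to 87109608) and of Rnf5 (chromosome 17, 34603227 to 34604500), inside Tbcel and Pym1, and 12.6 kb from Ifngr2, the gene of an interferon gamma receptor chain. The remaining regions of the 10 had Dph5, Hbs1l and Myc as nearest genes, at 71.4, 59.3 and 179 kb. Whether a region inside a gene was exonic or intronic was not resolved here.

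Libraries of the same factor resembled each other slightly more than libraries of different factors. The mean Jaccard index of covered bases was 0.598 over the 6 pairs within a factor and 0.562 over the 9 pairs between factors, a difference of 0.0355 (exact permutation test over the 10 splits, one-sided, p = 0.1, the smallest p the design allows). The direction depended on single libraries: the difference was -0.0051 without LEF1 replicate 1 and -0.0237 without LEF1 replicate 2. With the 11423 strongest peaks of each library it was 0.0567 (exact permutation p = 0.1, one-sided), and with lists of equal size among 5 libraries it was positive whichever library was left out, 0.0142 to 0.1125 (22901 peaks each without TCF1 replicate 3, otherwise 11423). TCF1 replicate 3 stood apart from all others, with indices of 0.268 to 0.428 against 0.581 to 0.744 among the other 5 libraries.

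**Figure D3:**
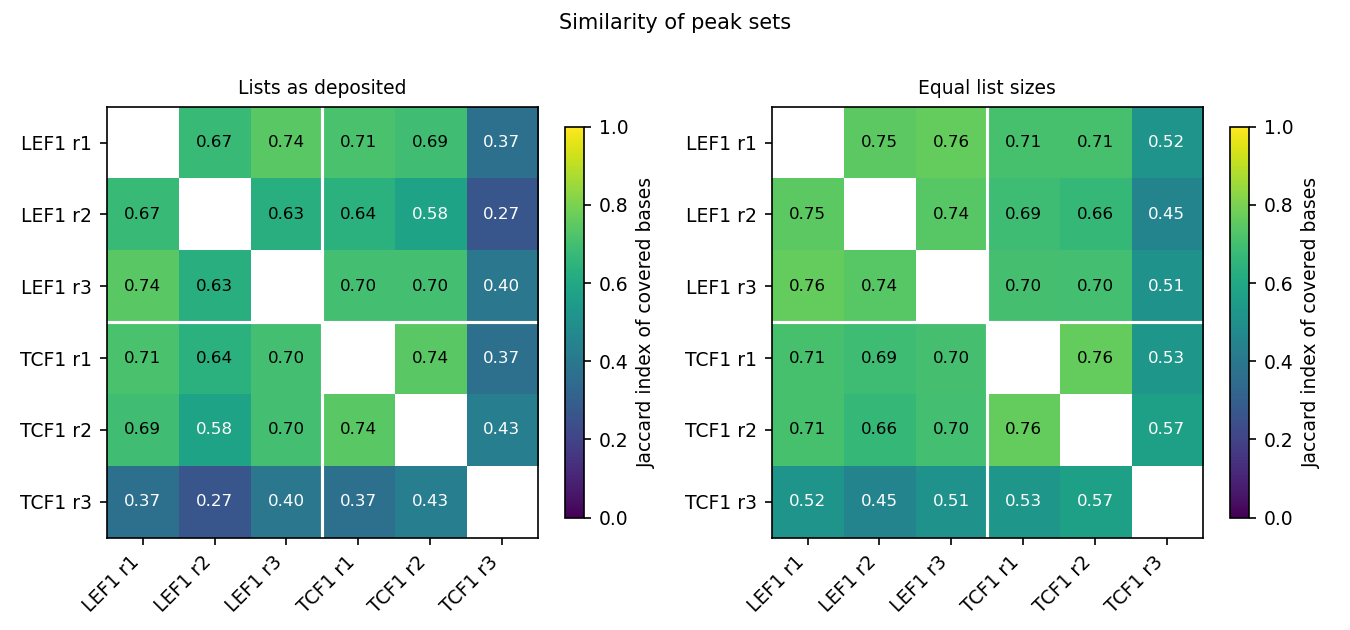
Jaccard index of covered bases for each pair of the 6 libraries, for the lists as deposited (left) and for equal list sizes (right), where r1 to r3 are replicates 1 to 3 and white lines part the factors. The row of TCF1 replicate 3 is the lowest in both panels, 0.268 to 0.428 on the left.

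The next comparison asked where in relation to genes each factor was found. TCF1 summits lay near the end of a protein-coding gene more often than LEF1 summits in every library. The share within 1 kb of either end was 23.9% ± 1.13 for LEF1 (SD, n = 3) and 29.3% ± 1.57 for TCF1 (SD, n = 3), against 2.98% of random positions. The groups did not overlap, and the difference of -5.46 percentage points, LEF1 minus TCF1, gave the smallest p that 3 against 3 libraries allow (exact permutation test, two-sided, p = 0.1). Summits inside genes but farther from the ends made up 43.8% ± 0.693 for LEF1 and 40.9% ± 1.12 for TCF1 (SD, n = 3), and those outside genes 32.4% ± 0.44 and 29.8% ± 0.446 (exact permutation test, two-sided, p = 0.1 for each). With equal list sizes the share near gene ends was 24.8% ± 0.355 for LEF1 and 30.1% ± 0.893 for TCF1 (SD, n = 3; exact permutation test, two-sided, p = 0.1).

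Regions held by one factor and not the other were then set against gene ends. Of the 739 regions held by TCF1 and not by LEF1, 65.2% lay within 1 kb of a gene end (95% exact binomial interval 61.7 to 68.7), against 13.0% (12.2 to 13.8) of the 6926 regions held by LEF1 and not by TCF1. Regions held by both lay between, at 28.0%. The odds of lying at a gene end were 12.5 times higher for TCF1-only than for LEF1-only regions (Fisher's exact test, two-sided, p = 2e-203), and 8.89 times higher with equal list sizes (59.6% of 1291 regions against 14.2% of 1337, Fisher's exact test, two-sided, p = 3.8e-135). Regions are not independent replicates, so these tests describe the 6 libraries and cover counting error only. With equal list sizes the gap was 45.36 percentage points, and the 9 splits that mix the factors, each with 2 libraries of one factor against 1, gave gaps of 31.92 to 38.14.

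**Figure D4:**
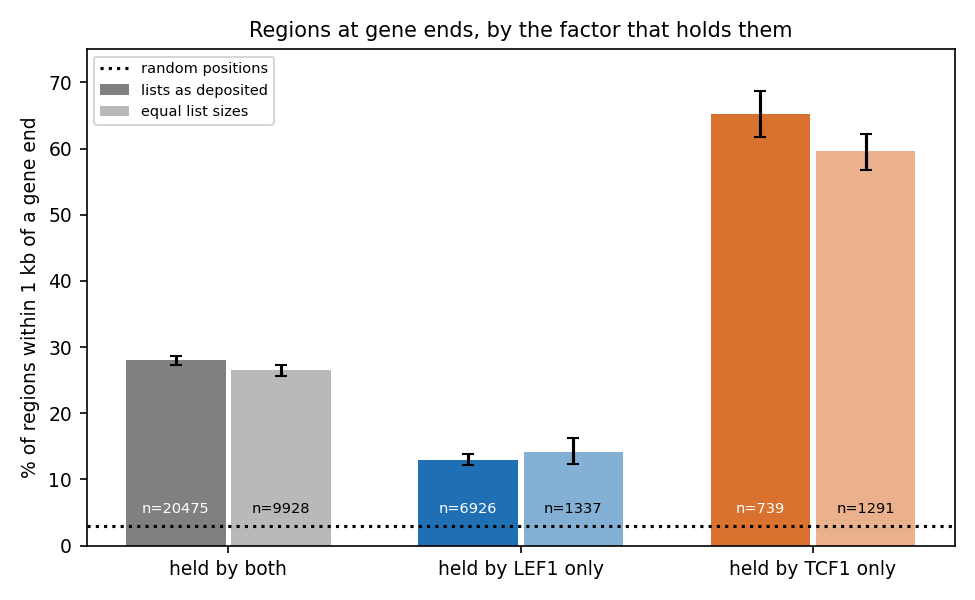
Percentage of regions within 1 kb of either end of a protein-coding gene, for regions held by both factors, by LEF1 only and by TCF1 only. Solid bars are the lists as deposited, pale bars equal list sizes, error bars 95% exact binomial intervals and the dotted line random positions (2.98%). TCF1-only regions reach 65.2% and 59.6%, LEF1-only regions 13.0% and 14.2%.

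Regions found in every library of one factor and in none of the other were then counted. LEF1 had 1202 such regions and TCF1 had 7. The 7 TCF1 regions all lay within 1 kb of an end of their nearest gene: Abhd16a, Ewsr1, Noct, Pdik1l, Ss18l1, Mrpl46 and Prkci. They were weak, with fold enrichments of 3.94 to 14.1. Their mean rank percentiles were 62.5 to 84.2, where low values are the strongest peaks, against 22.0 to 28.9 for the best 8 LEF1 regions. Of the 10 splits of the libraries into 3 and 3, 8 gave a count as large as 7, taking the larger side of each other split. In the other splits the side with TCF1 replicate 3, which has the short list, gave 0 or 1. Ewsr1 encodes an RNA-binding protein, Noct a circadian phosphatase and Prkci an atypical protein kinase C. The best-ranked LEF1 regions had lower ranks than the shared ones and lay mostly away from gene ends, for example 37.6 kb from Tigd2 (chromosome 6, 59249674 to 59250118, fold enrichment 17.1 to 29.5), inside Sntb2 (chromosome 8, 107002528 to 107002819) and 14.2 kb from the carnitine transporter gene Slc22a5. The others of the best 8 were nearest to Rsph3a, Rubcnl, Ebag9, Zfp787 and H2-Aa, the last a gene of MHC class II, whose region lay near one end of the gene. Of all 1202, 9.65% lay at a gene end (95% exact binomial interval 8.04 to 11.5).

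Lists of equal size remove any difference in the number of sites along with that in list length. The surplus of LEF1 regions was not kept when such lists were compared: 293 regions were then found in every LEF1 and no TCF1 library, and 398 the other way round. Of these, 10.6% (31 of 293) and 74.4% (296 of 398) lay at a gene end. The best-ranked LEF1 regions of these sets were nearest to Cul1, Cdc14b, Ablim1 and H2-Eb1, another MHC class II gene, and the best-ranked TCF1 regions lay at an end of Gnb2, of Frat1, a Wnt pathway gene, of Selenow and of Eif3b, a translation initiation factor gene. Leaving out a library loosens the rule for these counts, so they could hardly fall. In the lists as deposited, the TCF1 count rose from 7 to 150 without TCF1 replicate 3 and to 24 without LEF1 replicate 2. The LEF1 count was 3126 without LEF1 replicate 3 and 2553 without TCF1 replicate 1.

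Gene lists fixed beforehand were used to ask which genes the regions surround. Over the gene body and 10 kb on each side, genes of naive and stem-like T cells and of T cell identity carried the most regions relative to random lists. Random lists were matched on length and not on expression or open DNA. The folds therefore do not separate binding of the factors from genes that are open in these cells. Of the 25 naive and stem-like genes, 24 had a region of each factor. They held 11.3 LEF1 and 8.64 TCF1 regions per gene on average, 6.81 and 6.60 times the means of random lists matched on gene length (1.66 and 1.31; adjusted permutation p = 0.00065 for each, the smallest that 10000 random lists gave here). Foxp1, a factor that maintains quiescence of naive T cells, held 48 LEF1 and 38 TCF1 regions over 597 kb, and the survival gene Bcl2 held 19 and 15. All 20 genes of T cell and CD8 identity had regions of both factors, at 6.79 and 6.62 times the random means (adjusted permutation p = 0.00065 for each). Ets1 held 30 LEF1 and 21 TCF1 regions, the transcription factor gene Ikzf1 20 and 16, and Bcl11b, which is needed for commitment to the T lineage, 20 and 15. At gene ends alone the folds of these lists were about as high as those of some others: 3.41 (LEF1) and 3.44 (TCF1) for naive and stem-like genes and 3.48 and 3.37 for T cell identity, against 3.61 and 2.76 for cytokine receptors.

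Cytokine receptor genes held 4.90 times (LEF1) and 4.42 times (TCF1) the random means, with a LEF1 region at all 17 genes and a TCF1 region at 15. Tgfbr2, the gene of a TGF-beta receptor chain, led this list with 22 LEF1 and 17 TCF1 regions, followed by Tnfrsf1b (12 and 9). Il6ra (10 and 7), Il6st (10 and 7), Il21r (9 and 10) and Il4ra (10 and 5) came next, tied at 10 regions held by either factor. Homing and adhesion genes held 4.13 and 3.97 times the random means, with regions at 17 of 19 genes. Beside Ccr7 they included Gpr183 (10 and 6), a receptor for oxysterols, and the selectin ligand gene Selplg (9 and 7). The adjusted permutation p was 0.00065 for both factors in both lists.

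Effector and exhaustion genes held 2.29 times (LEF1, adjusted permutation p = 0.0022) and 2.42 times (TCF1, adjusted permutation p = 0.001) the random means, with regions of LEF1 at 29 and of TCF1 at 27 of 30 genes. Il2ra held 9 of each and Nr4a1, an early response gene of T cell receptor signalling, 8 and 6. Both calls of this list were lost at gene ends alone (1.55 and 1.575 times, adjusted permutation p = 0.0645 for each). Wnt pathway genes held 2.77 and 2.63 times the random means (adjusted permutation p = 0.001 and 0.0014), with regions of LEF1 at 13 and of TCF1 at 12 of 20 genes. Znrf3 (15 and 10) and Rnf43 (10 and 7), which encode ligases that remove Wnt receptors, stood with Lef1 and Tcf7 at the head of this list. The call of the Wnt list rested on the genes of the factors themselves: with Lef1 and Tcf7 left out, a setting chosen after the data were seen, the remaining 18 genes held 1.90 and 1.73 times the random means (adjusted permutation p = 0.069 and 0.11). The calls were also lost at gene ends alone (1.65 and 1.52 times, adjusted permutation p = 0.1 and 0.19).

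Housekeeping genes held 1.85 times (LEF1) and 1.99 times (TCF1) the random means (adjusted permutation p = 0.019 and 0.0044), with regions at 21 of 24 genes. Eef2 and Actb held 5 of each factor, and Snrpd3 4 and 3. The LEF1 call was lost with equal list sizes, when all 3 libraries were required and without LEF1 replicate 2 (1.51, 1.69 and 1.68 times, adjusted permutation p = 0.36, 0.076 and 0.076), and the TCF1 call with 50 kb around genes (1.53 times, adjusted permutation p = 0.06). At gene ends alone the folds were 2.83 and 2.89. Genes of CD4 and helper T cells did not pass the test (1.95 and 1.94 times, adjusted permutation p = 0.1 and 0.088), but passed with equal list sizes (2.51 and 2.39 times, adjusted permutation p = 0.0485 for each), and at gene ends alone their folds were 0.498 and 0.541. Among them Ctla4 held 6 LEF1 and 4 TCF1 regions, Gata3 5 and 4, and Foxp3 and Cd40lg 4 of each.

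Markers of other cell types served as comparison lists. B cell genes held 0.694 and 0.676 times the random means (adjusted permutation p = 0.58 and 0.56), with Cd79a and Cd72 at 3 of each factor and Bank1 at 3 and 1. Myeloid genes held 0.716 and 0.898 times (adjusted permutation p = 0.58 and 0.96), with Cd68 and Itgam at 3 of each, Spi1 at 3 and 2 and Fcgr3 at 2 of each. Erythroid and megakaryocyte genes held 0.405 and 0.587 times (adjusted permutation p = 0.18 and 0.51), with Klf1 at 3 of each, Epor at 1 of each and Tal1 at 0. With equal list sizes the LEF1 folds of the myeloid and erythroid lists were 1.21 and 0.958. Natural killer cell genes held 1.42 and 1.28 times (adjusted permutation p = 0.34 and 0.54), with Klrd1 at 5 and 4, Tyrobp at 4 of each, Klre1 at 4 and 3 and Klrk1 at 4 and 2. Genes of this receptor cluster are neighbours with similar sequences, so their counts overlap and are uncertain. Genes of non-haematopoietic tissues held 0.36 times (LEF1) and 0.379 times (TCF1) the random means (adjusted permutation p = 0.043 and 0.062). The LEF1 call was lost with equal list sizes (0.543 times, adjusted permutation p = 0.5) and with 50 kb around genes (0.668 times). It was also lost, with little change in the fold, at the stricter threshold (0.355 times), when all 3 libraries were required (0.383) and without any single LEF1 library (0.367 to 0.381, adjusted permutation p = 0.054 to 0.08). At gene ends alone these genes held 0 regions of either factor (adjusted permutation p = 0.0014 and 0.0017). Their leading members were Cela1 (4 and 3), Prm1 (2 of each), Fgb and Gfap (1 of each). At gene ends alone B cell genes passed below the random means (0.152 and 0.16 times, adjusted permutation p = 0.024 and 0.029), as did myeloid (0.17 times) and erythroid genes (0) for LEF1 and natural killer genes (0.175 times) for TCF1. In all, 15 of the 26 list tests passed (two-sided permutation test, genes drawn from length-matched pools for 10000 random lists, Benjamini-Hochberg adjustment over 26). Lists share members, and genes are not independent replicates.

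**Figure D5:**
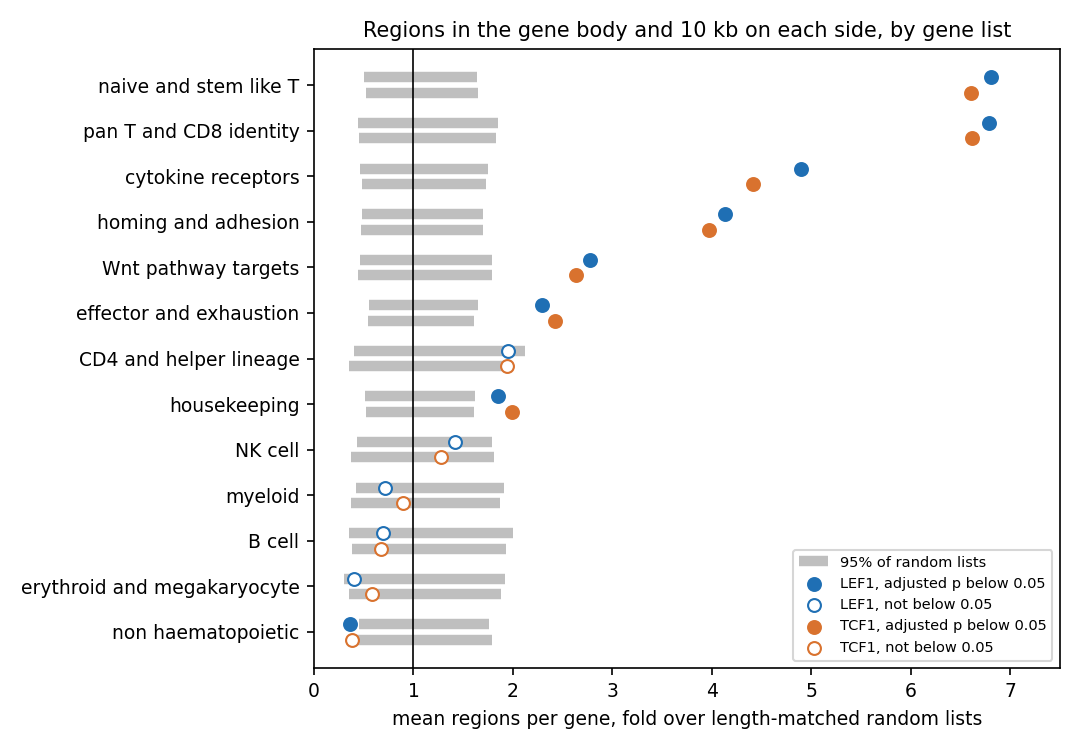
Mean number of regions per gene (gene body and 10 kb on each side) divided by the mean of 10000 length-matched random lists, for 13 gene lists and both factors. Grey bars span 95% of the random lists and filled points have an adjusted p below 0.05. Naive and stem-like genes lie at 6.81 (LEF1) and 6.60 (TCF1), non-haematopoietic genes at 0.36 and 0.379.

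A last comparison asked whether the factor-only regions surround different genes. Near genes of T cell and CD8 identity, 53 regions were held by LEF1 only and 0 by TCF1 only, against 5228 and 684 near other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 0.046 over 13 lists). The 53 regions included 9 at Ets1 and 5 at Bcl11b. Near naive and stem-like genes 69 were held by LEF1 only and 3 by TCF1 only (adjusted p = 0.32 by Fisher's exact test), and none of the other 12 lists passed. The call at T cell identity genes was lost with equal list sizes, with summits or reciprocal overlap in place of any overlap, when all 3 libraries were required, at gene ends alone, and without TCF1 replicate 1 or 2. The number of lists that passed was 3 without LEF1 replicate 1 and 2 with 50 kb around genes.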

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

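The depth test, the test without TCF1 replicate 3, the test of list length on factor-specific regions and the counts over other splits of those regions were set up as tests of a cause only after the results were seen. Equal list sizes and leaving out each library in turn had been planned as settings.

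Peaks outside chromosomes 1 to 19, X and Y entered no comparison: 23, 35 and 24 peaks in LEF1 replicates 1, 2 and 3, and 35, 27 and 11 in TCF1 replicates 1, 2 and 3. They were singled out because they are signal outside the main measurement with no control list to set against them. Of these, 2 in each library lay on the mitochondrial genome.

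TCF1 replicate 3 had the fewest peaks, 11423 against 22901 to 37646. Its depth relative to the control was 3.2319 and the highest of the other libraries was 2.8883, which argues against lower sequencing depth as the reason. A lower yield of cut fragments at the antibody's sites in that library may account for the short list, which was not tested. No biological explanation was tested.

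Summits lay at gene ends more often in TCF1 than in LEF1 libraries. With equal list sizes the difference was 5.296 percentage points, which argues against list length. It was 4.555 without TCF1 replicate 3, so that library alone does not account for it. Among the 2855 strongest peaks of each library it was 4.799 and the groups did not overlap, which argues against weak background at open gene starts. A difference in binding between the factors, and a difference between the antibodies in what else they recognise, may both give this pattern and stay open as untested.

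For regions held by one factor only, with equal list sizes, the gap in the share at gene ends was 45.36 percentage points in the real split and 31.92 to 38.14 in the 9 others, each of which still sets 2 libraries of one factor against 1, and 1 of the 10 splits, the real one, gave a gap as large. The 10 splits are too few for a share under 0.05.

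Many more regions were found in every LEF1 and no TCF1 library (1202) than the reverse (7). With equal list sizes the ratio of the LEF1 to the TCF1 count was 0.736. Equal sizes leave similar numbers of regions held by one factor only (1337 for LEF1, 1291 for TCF1). The surplus was thus likely to vanish whatever its cause. The test therefore cannot tell longer LEF1 lists from a larger number of LEF1 sites. For the lists as deposited, 1 of the 10 splits gave a LEF1 count as large and 8 of the 10 gave a TCF1 count as large, with 961 as the highest count of another split. The larger side of each other split was taken, mostly the side without the short list of TCF1 replicate 3. The sides with that list gave 0 or 1. The 8 of 10 therefore do not set the TCF1 count of 7 against like sides. With equal list sizes, 1 of the 10 splits gave a count as large for LEF1 (293) and 1 of the 10 for TCF1 (398), with 44 as the highest other. The 10 splits are too few for a share under 0.05.

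For the gene lists that differ between LEF1-only and TCF1-only regions, 3 of the 10 splits called as many lists as the 1 list of the real split, and the highest other split called 2. The 10 splits are too few for a share under 0.05.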

How the results depend on the processing

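Equal list sizes among 5 libraries and the shortened Wnt list were chosen only after the results were seen. Causes were not tested, except that equal sizes remove list length and stricter rules for holding or sharing remove regions. The gene-end difference kept its direction under all alternatives run (-5.96 to -4.555 when a library was left out, and -5.593 to -4.097 with equal sizes among 5 libraries), and the peak difference of 5410 to 12673.7 without single libraries stayed positive.

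The share of LEF1 regions held by TCF1 was 75.963% at the stricter threshold, 88.131% with equal sizes, 73.073% with reciprocal overlap, 72.234% with summits, 49.435% when all 3 libraries were required, and 39.94% to 86.403% without single libraries. The share of TCF1 regions held by LEF1 was 88.493% with equal sizes, 94.452% with reciprocal overlap, 94.372% with summits, 99.171% with all 3 libraries and 89.913% to 99.755% without single libraries.

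The count in every LEF1 and no TCF1 library was 293 with equal sizes and 1202 to 3126 without single libraries. The reverse count was 398 with equal sizes, 20 with reciprocal overlap, 77 with summits and 7 to 150 without single libraries. Leaving out a library loosens the rule for both counts, so they could hardly fall. With equal sizes among 5 libraries (11423 peaks each, but 22901 without TCF1 replicate 3, where list length changes too) the LEF1 counts were 415, 398 and 424 without LEF1 replicates 1, 2 and 3 and 436, 453 and 592 without TCF1 replicates 1, 2 and 3, and the TCF1 counts were 461, 460, 500, 549, 560 and 803 in that order.

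The within-minus-between similarity ran from -0.0237 to 0.1164 without single libraries, being -0.0051 without LEF1 replicate 1. Of the 15 list calls, 13 to 15 were kept without single libraries, 14 at the stricter threshold, 13 with all 3 libraries and 13 with equal sizes, where 2 others passed (CD4 and helper genes). At gene ends only 17 passed, 11 of them among the 15: the effector and Wnt calls were lost, and lists of other cell types passed below the random means. The lists that differ between factor-only regions numbered 0 with equal sizes, reciprocal overlap, summits, all 3 libraries or gene ends only, 2 with 50 kb around genes, and 0 to 3 without single libraries. With 0.5 added to each count, the odds ratio at T cell identity genes was 14.008, and 0.527 to 17.717 without single libraries, below 1 without TCF1 replicate 1 or 2 (0.527 and 0.528), where few regions were held by TCF1 alone and the added 0.5 sets the value. At gene ends only, natural killer genes held 0.175 times the random mean of TCF1 regions (adjusted permutation p = 0.04), against 1.281 times in the gene body and 10 kb.

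With the replicate numbers as pairs (replicate block, exact sign-flip test, smallest p 0.25), the peak difference of 9689.7 and the gene-end difference of -5.457 each gave p = 0.25. The numbers are those of the sample titles, while the library names carry other numbers (LEF1 2 to 4, TCF1 4 to 6). LEF1 and TCF1 libraries with the same title number correlated at 0.145, -0.191 and -0.122, and those with different numbers at -0.191 to 0.254. The correlations do not measure the overlap of the lists. By the Jaccard index the same-number pairs overlapped at 0.712, 0.581 and 0.396. The correlations give no sign that the numbers pair the libraries. With 3 libraries per factor they cannot exclude it. Motif and repeat alternatives were not run, and equal sizes leave no peak difference to compute. Unknown absolute depth limits any statement on missing peaks.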

Other observations

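The gene families, transcript types and loci of this part were chosen after the main results were seen, and 2 of the 12 families tested are left out because genes with many regions were seen before they were chosen. The Gimap genes, which encode GTPases of lymphocyte survival, held 6.75 LEF1 and 5.25 TCF1 regions per gene, 6.85 and 6.15 times the means of length-matched random lists (adjusted permutation p = 0.00032 for each over 24 tests, two-sided), and all 8 had a region at a gene end. These 8 genes are neighbours and share regions. Many histone, olfactory receptor, chemokine receptor and keratin genes also lie in clusters, while random genes were drawn singly over the genome. The p-values of these families may therefore be too small. Mitochondrial ribosomal protein genes, proteasome subunit genes and Zfp zinc finger genes did not pass the test of regions per gene (LEF1 1.16, 1.27 and 0.884 times, adjusted permutation p = 0.31, 0.26 and 0.13), while interleukins and their receptors passed for LEF1 (1.40 times, adjusted permutation p = 0.039) and not for TCF1 (1.25 times, adjusted permutation p = 0.16). Histone genes held 1.87 and 1.92 times the random means (adjusted permutation p = 0.00032 for each), and 56.9% of 102 had a LEF1 region at an end against 28.4% in random lists (adjusted permutation p = 0.00048). Chemokine receptor genes, some of them in the homing list, held 2.98 and 2.81 times the random means (adjusted permutation p = 0.00032 and 0.0006), and did not pass in the share at gene ends (adjusted permutation p = 0.64 for each). Cytosolic ribosomal protein genes were occupied at their ends, 76.2% of 84 genes having a region of each factor there, against 28.1% (LEF1) and 27.1% (TCF1) of random lists (adjusted permutation p = 0.00048). For LEF1 the share was 61.5% of both the mitochondrial ribosomal and the proteasome genes, against 33.8% and 37.7% (adjusted permutation p = 0.00048 and 0.0069). Zfp genes passed there for LEF1 (44.7% against 38.7%, adjusted permutation p = 0.036) and not for TCF1 (43.3% against 37.9%, adjusted permutation p = 0.058). Olfactory receptor genes, which are expressed mainly in olfactory neurons, had a LEF1 region at an end in 0.81% of 1106 genes against 6.35% in random lists (adjusted permutation p = 0.00048), and none of 49 keratin genes had one.

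Within 10 kb, the T cell receptor constant genes Trac, Trbc1, Trbc2 and Trdc had 11, 9, 11 and 8 LEF1 regions and 8, 7, 8 and 6 TCF1 regions, while the immunoglobulin constant gene Igkc had 0 and Ighm 1 of each. The T cell receptor gamma constant genes Trgc1, Trgc3 and Trgc4 also had 0, and Trgc2 had 1 of each. These counts were not tested. Trbc1 and Trbc2 are near-identical neighbours, so their counts share regions and are uncertain. Of 408 tRNA genes, 42.2% had a LEF1 region and 38.2% a TCF1 region within 1 kb, against 3.1% at random positions for LEF1. Pseudogenes lay below their random value, with 2.38% of 9944 near a LEF1 region against 4.04%. Beyond the fixed lists, Ubac2 (40 LEF1 and 30 TCF1 regions), Sgms1 (36 and 22) and Arhgef3 (35 and 25) followed Foxp1 among the genes with the most regions, and the Ubac2 interval contains Gpr183. LEF1 regions numbered 3.1 per Mb on chromosome X and 8.38 to 17.7 per Mb on the autosomes.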
